A study of Homo sapiens with 9 samples.

How the data were processed

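The series holds 9 RNA-seq libraries of A549, a human lung adenocarcinoma cell line. The labels divide them into 3 groups of 3: cells given the empty Lenti-CRISPR-V2 plasmid (NC), cells given a plasmid directed at OGT (OGT_KO), and cells given a plasmid directed at TR11B (TR11B_KO). TR11B is the UniProt entry name of osteoprotegerin, and the targeted gene was therefore taken to be TNFRSF11B; the labels themselves give no other name. The labels give NC the genotype WT, and its table columns are named WT, while its treatment label names the empty plasmid, which was followed here. Groups and replicate numbers came from the sample titles. The titles call the samples biological replicates, but no label says that they came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical. Guide sequences and clone numbers were not given in the sources used here. The columns of each knockout carry a single name with the replicate number added. Effects of a guide or clone, or of edits off the target, therefore cannot be told apart from those of the knockout.

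Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, total RNA was extracted with TRIzol, and libraries were made with the VAHTS Universal V6 RNA-seq kit. Whether strand was kept, and how many reads mapped outside genes, was not given in the sources used here. Per the submitters' processing notes, the tools were fastp, HISAT, HTSeq, R 3.2.0 and DESeq2, with the GRCh38 build. No role, order or setting of these tools was given. The deposited count table holds whole-number reads per gene with no normalization by the authors, and the second deposited table holds the authors' FPKM values, scaled to gene length and library total, for the same 19257 genes. Of these genes, 1334 had no count in any library. The ratio of the deposited FPKM to the count gave the gene length used by the authors, which came within 0.01 base of a whole number for 17919 of the 17923 genes with a count. Genes that share sequence with close copies, or that overlap on opposite strands, are uncertain, since the counting of such reads was not described.

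Gene positions came from the RefSeq annotation of GRCh38.p14. It matched 18561 of the 19257 gene names, 18339 by symbol and 222 by a single synonym. GC content was that of the longest GENCODE transcript of each gene, and was found for 16650 genes. Genes were assigned to chromosome arms by position.

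Library totals ranged from 38327508 to 42245970 counts. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Its filterByExpr step kept 12574 genes, TMM factors scaled the libraries, and the robust quasi-likelihood F test was fitted to all 9 libraries with 1 mean per group, so that the groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale, and standard errors (SE) were taken as the absolute log2 fold change divided by the square root of F. The prior degrees of freedom had a median of 8.32, and the biological coefficient of variation was 0.241. Levels are TMM-normalized CPM, counts per 1e6 counts of the scaled library total.

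Before the data were examined, 45 gene lists were fixed for pathways, complexes, lineages and cell types. Of these, 41 had at least 5 tested members and were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera was repeated with the correlation estimated for each list, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Members were counted by the per-gene test, adjusted over all genes and adjusted over the list alone.

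The genes named here followed a rule fixed at the same time. OGT, TNFRSF11B and OGA were always taken. For each knockout against NC, the rule added the 8 genes with the largest rise and the 8 with the largest fall. Eligible genes had an adjusted p under 0.05, an average log2 CPM of at least 2, and all 3 knockout libraries on the same side of all 3 NC libraries. It added 5 and 5 for the knockouts against each other, up to 4 members with the smallest adjusted p of each list with at least 3 called members or a camera call, 2 of other lists, and the 8 genes per direction changed alike in both knockouts and 5 changed in opposite directions. Not all of them are named.

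Both knockouts were compared with the same NC libraries. Unchanged groups were therefore simulated against NC in 20 runs, and the overlap of independent lists was computed per direction. The NC libraries were too few to be split into parts of 2.

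Alternatives fixed beforehand were DESeq2 1.42.0 with its own size factors, RLE size factors, library totals alone, no low-count filter, a filter of CPM at least 1 in 3 libraries, fits of only the 2 groups compared, the replicate number as a block, each library left out in turn, limma on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 libraries, the same with a pseudocount of 0.1 or with no FPKM filter, a 2-fold threshold and an adjusted p under 0.01. After the data had been seen, offsets were added for trends with gene length and GC content, fitted per library as splines with 8 degrees of freedom, singly and together.

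The pipeline was tested on simulated counts drawn from the real means and library sizes. In the simulation of OGT_KO against NC, on 12366 genes, the test recovered 1 of 50 genes raised 1.5-fold, 25 of 50 raised 2-fold, 45 of 50 raised 4-fold and 11 of 50 lowered to 0.5 of their level, with 5 false calls. In that of TR11B_KO against NC, on 12348 genes, the numbers were 1, 23, 41 and 18 of 50, with 4 false calls. A simulated length trend gave 2824 calls without the length offset and 0 with it in edgeR. Intervals of summed counts are exact Poisson intervals at the 95% level and cover counting error only. Bootstrap intervals at the 95% level resampled genes with the libraries held fixed. They do not cover variation between libraries, and the genes are not independent replicates. Figures were drawn with matplotlib 3.10.9.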

Results

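RNA from 9 samples of A549 cells was sequenced to ask how knocking out OGT or TR11B changes gene expression in this lung adenocarcinoma line. NC, OGT_KO and TR11B_KO were each represented by 3 libraries. The count totals of replicates 1, 2 and 3 were 41403795, 42245970 and 38721903 for NC, 41307039, 38327508 and 39832578 for OGT_KO, and 41920820, 39556504 and 41063745 for TR11B_KO. The first principal component of log CPM held 41.8% of the variance, the second 24.2% and the third 12.6%. Rank correlations across genes between libraries of 1 group were 0.987 to 0.99 in NC and 0.989 to 0.99 in OGT_KO, but 0.96, 0.983 and 0.97 in TR11B_KO. TR11B_KO replicate 2 stood apart from the other libraries. Its TMM factor was 0.784 where the others lay between 0.951 and 1.159, and 14128 genes had a count in it against 14581 to 14954 elsewhere. Counts of replicate pairs differed by far more than sampling noise in every group, with a chi-square per degree of freedom from 9.5 to 309.9, so no library was a copy of another.

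The targeted genes were examined first in every library. OGT encodes the only enzyme that adds O-linked N-acetylglucosamine to nuclear and cytosolic proteins, and lies on chromosome X from 71533104 to 71575892 in GRCh38. It had 1239, 1143 and 967 counts in NC, 927, 1255 and 960 in OGT_KO, and 716, 356 and 484 in TR11B_KO. The OGT level was 27.1 ± 2.45 CPM (SD, n = 3) in NC, 24.1 ± 3.74 in OGT_KO and 13.6 ± 2.98 in TR11B_KO. In the edgeR test, OGT had a log2 fold change of −0.17 ± 0.21 (SE) in OGT_KO against NC (adjusted p = 0.607), and it fell in TR11B_KO against NC by 0.99 ± 0.21 (adjusted p = 0.00393). OGT was thus higher in OGT_KO than in TR11B_KO, by 0.82 ± 0.21 (adjusted p = 0.00882). That difference did not pass the test without OGT_KO replicate 2 (0.69, adjusted p = 0.0581), with the length offset (0.39, adjusted p = 0.134) or with both offsets (0.19, adjusted p = 0.305), and its highest adjusted p over the alternatives was 0.305. With both offsets, the log2 fold change of OGT in OGT_KO was −0.45 (adjusted p = 0.0258), in a range from −0.45 to −0.05 over all alternatives with a highest adjusted p of 0.92.

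TNFRSF11B encodes osteoprotegerin, a secreted decoy receptor for RANKL and TRAIL, and lies on chromosome 8 from 118923557 to 118951885. It had 13, 15 and 3 counts in NC, 1, 0 and 0 in OGT_KO, and 3, 1 and 0 in TR11B_KO, and was too low to be tested in the model. Summed counts were 31 in NC, 1 in OGT_KO and 4 in TR11B_KO. Relative to NC this was a ratio of 0.033 (95% interval 0.000811 to 0.198) for OGT_KO and 0.129 (0.033 to 0.364) for TR11B_KO. The exact two-sided permutation test over libraries gave p = 0.1 in both comparisons, the smallest value that 3 against 3 allows. A CRISPR edit need not lower the mRNA of its gene, so these levels neither check nor contradict the edits by themselves. Because OGT did not pass as lower in its own group in the edgeR test without offsets, and TNFRSF11B was low in both, OGT_KO and TR11B_KO below stand for the libraries labelled so, and every direction rests on those labels.

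OGA, which encodes the enzyme that removes O-GlcNAc (chromosome 10, 101784450 to 101818444), had 202, 213 and 154 counts in NC, 95, 139 and 44 in OGT_KO, and 157, 75 and 216 in TR11B_KO. It fell in OGT_KO by 1.12 ± 0.37 (adjusted p = 0.0474). This OGA call was lost under 9 of 20 alternatives, with adjusted p up to 0.186. Among them, OGA gave −1.08 without NC replicate 1 (adjusted p = 0.129), −1.05 without NC replicate 2 (0.134), −1.22 without NC replicate 3 (0.0777), −1.13 without OGT_KO replicate 1 (0.129) and −0.80 without OGT_KO replicate 3 (0.169). In TR11B_KO the value for OGA was −0.23 ± 0.36 (adjusted p = 0.662), and the direct difference between the knockouts was −0.88 (adjusted p = 0.0778, and 0.00264 to 0.402 over its alternatives). It passed in 8 of 20 alternatives, among them DESeq2 and each offset fit, and also without OGT_KO replicate 2 (−1.28, adjusted p = 0.0429) and without TR11B_KO replicate 2 (−1.16, adjusted p = 0.00264).

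**Figure D1:**
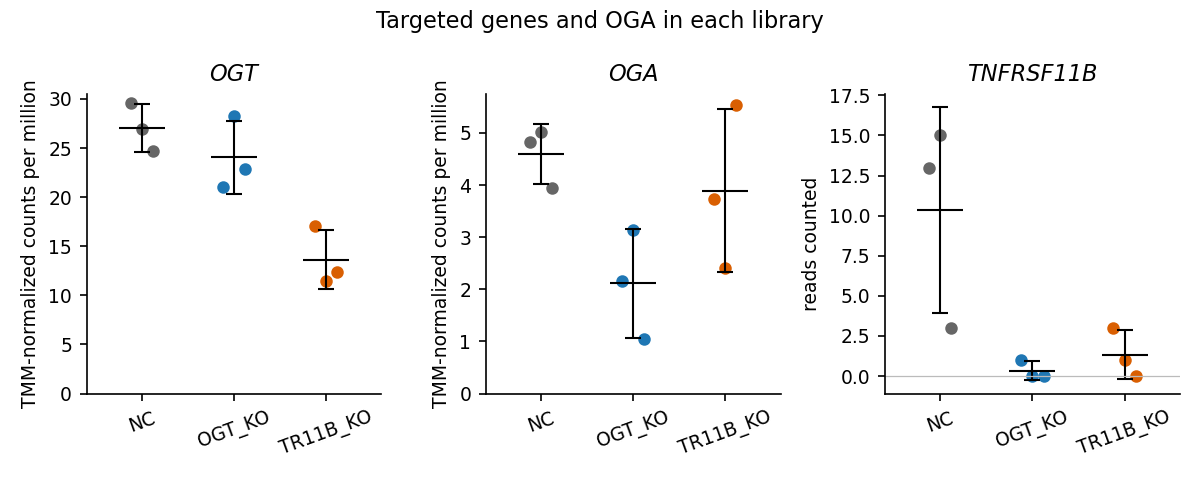
OGT and OGA in TMM-normalized CPM and TNFRSF11B in reads counted, in each of the 3 libraries of NC, OGT_KO and TR11B_KO (points), with the group mean (long line) and SD (short lines). OGT averaged 27.1 CPM in NC, 24.1 in OGT_KO and 13.6 in TR11B_KO.

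The libraries labelled OGT_KO were compared with NC to ask which genes change with OGT knockout. Several genes that were well expressed in NC were close to undetected in OGT_KO. SPATC1L had 982, 1041 and 994 counts in NC and 1, 1 and 3 in OGT_KO, a ratio of 0.0017 (95% interval 0.000551 to 0.00397), and TMEM98 had 325, 299 and 351 against 11, 3 and 0, a ratio of 0.0147 (0.00801 to 0.0248). SMO, the signal transducer of the Hedgehog pathway, fell by 4.81 ± 0.29 (SE) on the log2 scale, from 27.5 ± 1.54 to 0.976 ± 0.25 CPM (SD, n = 3; adjusted p = 2.26e-07 in edgeR). NNMT, which methylates nicotinamide, fell by 4.09 ± 0.23 (adjusted p = 1.5e-07). Among genes that rose, VCAN, the matrix proteoglycan versican, went from 26.1 ± 4.77 to 133 ± 23.6 CPM (log2 fold change 2.35 ± 0.34, adjusted p = 0.000468), and TNC, tenascin C, rose by 2.24 ± 0.26 (adjusted p = 8.94e-05).

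Other large falls were those of MARCHF4, a membrane-bound ubiquitin ligase (−4.87), the kinase gene WNK2 (−3.70) and the p53 target PHLDA3 (−3.33). Other large rises were those of RTBDN (2.65), the angiogenesis inhibitor VASH1 (2.39), the kinase gene SBK1 (2.32), SMARCD3, a subunit of SWI/SNF chromatin remodelling complexes (2.28), and the HES family gene HES7 (2.16). In all, edgeR called 2303 of 12574 tested genes, 1039 higher and 1264 lower, of which 1230 changed at least 2-fold. All 3 OGT_KO libraries lay on 1 side of all 3 NC libraries for 49.8% of the tested genes, where chance gives 10%. The count was 1072 without NC replicate 1, 1169 without NC replicate 2, 1447 without NC replicate 3, 1162, 1170 and 1249 without OGT_KO replicate 1, 2 and 3, and 4536 without TR11B_KO replicate 2, whose spread enters the shared estimate. Without TR11B_KO replicate 1 the count was 3341, with 1577 genes higher. A fit of only OGT_KO and NC called 5095. Scaling by library totals alone moved the median log2 fold change to 0.147 from 0.032 and gave 1369 higher and 890 lower genes.

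Of the 41 lists tested by camera, 6 were called in OGT_KO, and 0 with an estimated correlation, where 5 passed an unadjusted p under 0.05; fry passed 18. Genes of cholesterol synthesis and uptake rose: of 24 tested, 9 rose and 0 fell (13 and 1 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.00291, and adjusted p = 0.197 with an estimated correlation). Among them were CYP51A1, the lanosterol demethylase (1.18 ± 0.24), and INSIG1, the sterol-regulated retention protein of the SREBP pathway (0.91 ± 0.17). In TR11B_KO the cholesterol list was not called, but its median was 0.405, and with the length offset 9 rose and 2 fell. In the list of lipid handling, which was not called (adjusted p = 0.698), 6 of 20 rose and 3 fell (6 and 5 adjusted over the list alone). CPT1A, which admits fatty acids into mitochondria, rose by 1.72, the desaturase gene SCD rose by 1.23, and DGAT2, a triglyceride synthase, fell by 2.35. Of 13 tested epithelial markers, 7 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.94, adjusted p = 0.0152, and adjusted p = 0.405 with an estimated correlation). CLDN4 rose by 3.43 ± 0.67 from 0.169 CPM, desmoplakin (DSP) by 1.35 ± 0.22 and CLDN1 by 0.94 ± 0.17, while KRT8, an abundant keratin of simple epithelia, fell by 0.99 ± 0.18, from 11460 to 5778 CPM.

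MYC and genes of ribosome biogenesis fell: 8 of 30 fell and 0 rose (9 and 0 adjusted over the list alone; median −0.42, adjusted p = 0.00291, and adjusted p = 0.405 with an estimated correlation). MYC itself fell by 1.46 ± 0.31 (adjusted p = 0.00523, and 0.0714 in limma on FPKM + 1 with no filter, the highest of its alternatives), the RNA polymerase I subunit gene POLR1G by 1.21 ± 0.19, fibrillarin (FBL) by 0.97 ± 0.16 and the rRNA methyltransferase gene NOP2 by 0.96 ± 0.15. In TR11B_KO this list was not called (median −0.105). There MYC (41.18, 12.9 and 32.37 CPM) and NOP2 (125.4, 139 and 127 CPM) also lay below all NC libraries, while POLR1G and FBL did not. Of 26 tested replication-dependent histone genes, 5 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of −0.71 (adjusted p = 0.0163, and adjusted p = 0.405 with an estimated correlation). This list did not pass without TR11B_KO replicate 2 (adjusted p = 0.0537). Its transcripts lack poly(A) tails, its genes are near-identical copies, and H3C4 fell by 1.48 ± 0.29 from only 4.64 CPM. Of 21 TGF-beta/SMAD targets, 8 fell and 1 rose (9 and 2 adjusted over the list alone; median −0.49, adjusted p = 0.0428, and adjusted p = 0.405 with an estimated correlation), among them LTBP2 (−1.70), TGFBI (−1.29) and ID3 (−1.24). The TGF-beta call was lost without OGT_KO replicate 2 (adjusted p = 0.0649) and in 4 other settings, with adjusted p up to 0.143. Of the 13 mitochondrially encoded genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.45, adjusted p = 0.0467, and adjusted p = 0.763 with an estimated correlation), led by the overlapping genes ATP6 (1.05) and ATP8 (0.99). This call was lost without NC replicate 1, NC replicate 3, OGT_KO replicate 2 or TR11B_KO replicate 3 (adjusted p up to 0.134) and in 4 other settings (up to 0.17). The share of counts from mitochondrial genes was 2.02 ± 0.172% (SD, n = 3) in NC, 2.86 ± 0.364% in OGT_KO and 1.96 ± 0.301% in TR11B_KO.

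In the hexosamine and O-GlcNAc list, 5 of 14 genes fell and 0 rose, also when adjusted over the list alone, and the list was not called (median −0.33, adjusted p = 0.0952). GFPT2, an isoform of the rate-limiting enzyme of the hexosamine pathway, fell by 1.71 ± 0.35 (adjusted p = 0.00469). Matrix, laminin and integrin genes moved both ways, with 5 of 24 rising and 6 falling (7 and 10 adjusted over the list alone; adjusted p = 0.634). LAMB3 rose by 2.04 and LAMB1 by 1.91, whereas perlecan (HSPG2) fell by 3.19. The matrix proteases and inhibitors were divided as well, with 4 of 19 rising and 3 falling (4 and 5 adjusted over the list alone; adjusted p = 0.698), and both TIMP2, a metalloproteinase inhibitor (−2.95), and PLAUR, the urokinase receptor (−2.23), fell. Of 26 p53 targets, 5 rose and 2 fell (8 and 6 adjusted over the list alone; adjusted p = 0.807), with rises of GDF15 (1.58) and CDKN1A (0.84) and falls of PHLDA3 and AEN (−1.07). CSF1, macrophage colony-stimulating factor, fell by 3.17 ± 0.30, in a list of tumour-secreted bone-acting factors of which 3 of 11 fell and 0 rose, the same counts as adjusted over the list alone (adjusted p = 0.144).

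**Figure D2:**
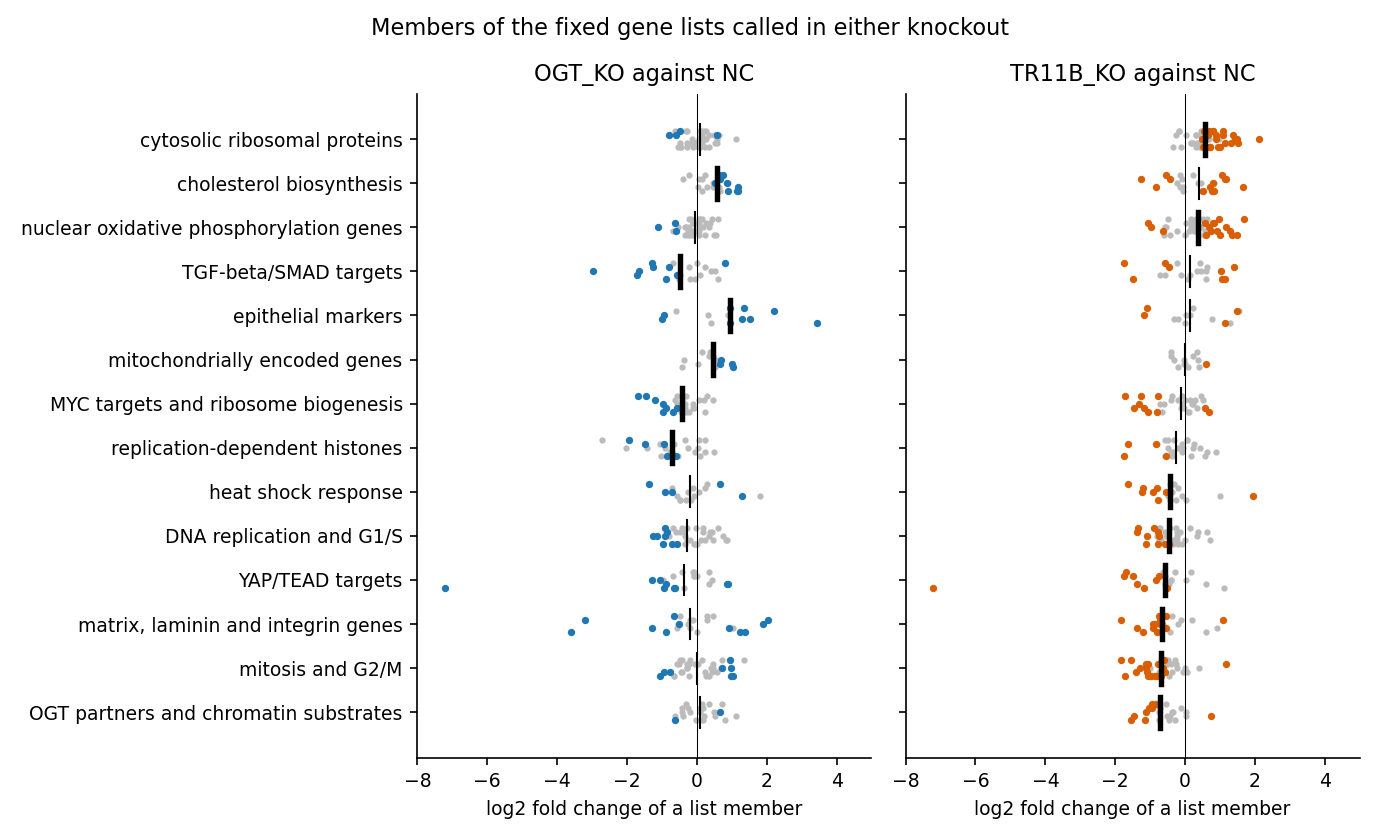
Log2 fold changes of the tested members (points) of the fixed lists called by camera in either knockout, in OGT_KO and TR11B_KO against NC. Coloured points passed the per-gene test, the black line is the list's median, and a thick line marks a called list. The median of the ribosomal protein genes was 0.56 in TR11B_KO, and that of cholesterol synthesis was 0.58 in OGT_KO.

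The libraries labelled TR11B_KO were compared with NC in the same way, to ask which genes change with TR11B knockout. TGM2, tissue transglutaminase, fell by 2.63 ± 0.19 (SE), from 1931 ± 89.7 to 313 ± 69.0 CPM (SD, n = 3; adjusted p = 4.05e-06 in edgeR). PDGFB, the B chain of platelet-derived growth factor, complement C3, and MAP3K14, the kinase NIK of the alternative NF-kB pathway, fell too, with log2 fold changes of −2.71 ± 0.21, −2.63 ± 0.20 and −2.46 ± 0.17 (adjusted p = 6.14e-06, 4.05e-06 and 2.99e-06). LTB, lymphotoxin beta, rose by 3.77 ± 0.25, from 5.02 ± 0.517 to 68.7 ± 16.7 CPM (adjusted p = 2.99e-06). PHLDA3, which fell in OGT_KO, rose here by 3.04 ± 0.37 (adjusted p = 0.000165).

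The fall of ANXA3, annexin A3, was 3.99 ± 0.44, to 0.621 CPM, that of AFAP1L2 was 2.95 ± 0.24, that of EPAS1, which encodes HIF-2 alpha, was 2.93 ± 0.39, and that of the ADP-dependent glucokinase gene ADPGK was 2.44 ± 0.33. Rises included those of the junctophilin gene JPH3 (3.2), the stress keratin KRT16 (3.14), RTN4RL2, a Nogo receptor relative (2.79), DIPK1B (2.56), PIK3IP1, an inhibitor of PI3 kinase (2.35), and SHF (2.35). In all, edgeR called 3469 of 12574 genes, 1666 higher and 1803 lower, of which 1745 changed at least 2-fold. Groups did not overlap for 40.9% of the tested genes, where chance gives 10%. The count was 1866 without NC replicate 1 and 1813 without NC replicate 2. Without TR11B_KO replicate 1 it was 4463, and 4386 without replicate 2, the library that stood apart, but 2723 without replicate 3. A fit of only TR11B_KO and NC called 2251, fewer than the 5095 of OGT_KO fitted the same way. The numbers of calls therefore do not rank the 2 knockouts. Scaling by library totals alone moved the median log2 fold change to −0.152 from −0.01 and gave 1180 higher and 2030 lower genes. RLE size factors moved the median the other way, to 0.049, with 3495 calls.

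Fold changes in TR11B_KO followed gene length. Across 12574 genes, which are not independent replicates, the rank correlation of log2 fold change with length was −0.313, against 0.066 in OGT_KO, and −0.407 against −0.047 among genes with an average log2 CPM of at least 2. Ranked by length into 5 groups, the shortest genes (111 to 2047 bases) had a median of 0.42 in TR11B_KO and the longest (7154 to 47609 bases) −0.31. With GC content the correlation was 0.15 in TR11B_KO and −0.234 in OGT_KO, but 0.236 and −0.052 among those higher genes. Taken by library, the deviation from the mean of all libraries had correlations with GC content of −0.14, 0.357 and 0.312 in TR11B_KO, which differ in sign.

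**Figure D3:**
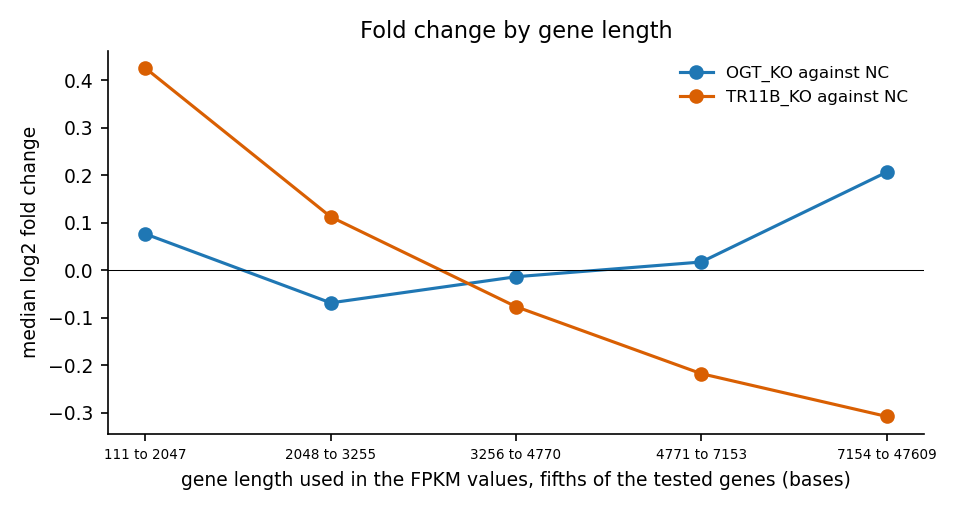
Median log2 fold change of tested genes in 5 groups ranked by the gene length used in the FPKM values (bases), for OGT_KO and TR11B_KO against NC. The TR11B_KO medians run from 0.42 for the shortest genes to −0.31 for the longest, and the OGT_KO medians from 0.08 to 0.21, with the lowest, −0.07, in the second group.

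Of the 41 lists, 8 were called in TR11B_KO, and 0 with an estimated correlation, where 5 passed an unadjusted p under 0.05; fry passed 25. Cytosolic ribosomal protein genes rose: of 46, 25 rose and 0 fell (29 and 0 adjusted over the list alone; median 0.56, adjusted p = 1e-08, and adjusted p = 0.381 with an estimated correlation). RPS23 rose by 1.42 ± 0.22, RPL27 by 1.38 ± 0.18 and RPS3 by 1.13 ± 0.17, although reads of these genes can be shared with processed pseudogenes. Counts of 81 ribosomal protein genes made up 14.8 ± 1.46% of TR11B_KO, 11.3 ± 0.291% of OGT_KO and 10.3 ± 0.421% of NC (SD, n = 3). The listed genes were short, with a median of 1160 bases against 3965 for all tested genes, and with the length offset their median was 0.19, with 12 rising and 1 falling (adjusted p = 0.0111). Of 38 nuclear oxidative phosphorylation genes, 14 rose and 3 fell (16 and 5 adjusted over the list alone; median 0.38, adjusted p = 0.0161, and adjusted p = 0.471 with an estimated correlation), with rises of COX7A2 (1.48) and NDUFA1 (1.35) and a fall of the ATP synthase subunit gene ATP5F1B (−1.06). That call was lost with the length offset (adjusted p = 0.728, the highest of its alternatives), with both offsets (adjusted p = 0.388) and without TR11B_KO replicate 1 (adjusted p = 0.112).

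Genes of cell division fell. Of 36 mitosis genes, 19 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of −0.69 that was −0.74 with the length offset (adjusted p = 5.12e-06, and adjusted p = 0.381 with an estimated correlation). The checkpoint kinase gene BUB1 fell by 1.83 ± 0.28, cyclin B1 (CCNB1) by 1.71 ± 0.29, and the kinesin genes KIF23 and KIF2C by 1.29 ± 0.23 and 1.10 ± 0.22. Of 36 DNA replication genes, 10 fell and 0 rose, also when adjusted over the list alone (median −0.46, adjusted p = 0.00313, and adjusted p = 0.444 with an estimated correlation). They included the ribonucleotide reductase gene RRM1 (−1.37) and the replicative helicase genes MCM4 (−1.08) and CDC45 (−0.89). In OGT_KO, 8 of the DNA replication genes fell and 0 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0933), and 5 mitosis genes rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.915).

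Among 23 OGT partners and chromatin substrates, 9 fell and 1 rose in TR11B_KO (10 and 1 adjusted over the list alone; median −0.71, adjusted p = 0.000494, and adjusted p = 0.381 with an estimated correlation). The nucleoporin genes NUP62 and NUP98 fell by 1.54 ± 0.20 and 1.47 ± 0.24, and HCFC1, which encodes a protein cleaved by OGT, fell by 1.14 ± 0.21. These genes were long, with a median of 7500 bases, and their median fold change was −0.47 with the length offset, where 8 fell and 1 rose. In OGT_KO, 1 rose and 1 fell (0 and 0 adjusted over the list alone). YAP/TEAD targets fell, with 10 of 21 lower and 0 higher (12 and 1 adjusted over the list alone; median −0.56, and −0.36 with the length offset, where 7 fell and 1 rose; adjusted p = 0.000494, and adjusted p = 0.431 with an estimated correlation), among them TGFB2 (−1.75), the Hippo kinase gene LATS2 on 13q (−1.70), AMOTL2 (−1.48) and MYOF (−1.37). Matrix, laminin and integrin genes fell, with 13 of 24 lower and 1 higher (16 and 3 adjusted over the list alone; median −0.66, and −0.44 with the length offset, where 7 fell and 2 rose; adjusted p = 0.000687, and adjusted p = 0.381 with an estimated correlation), including thrombospondin 1 (THBS1, −1.83), LAMA5 (−1.39) and LAMB1 (−0.91). Of 18 heat shock genes, 7 fell and 1 rose, also when adjusted over the list alone (median −0.43, adjusted p = 0.0403, and adjusted p = 0.471 with an estimated correlation). DNAJB1 fell by 1.63, HSPA8 by 1.23 (adjusted p = 0.00967, and 0.0555 in limma on FPKM + 1 with no filter, the highest of its alternatives) and HSPH1, on 13q, by 1.21, and the mitochondrial chaperonin gene HSPE1 rose by 1.94. This call was lost without NC replicate 2, NC replicate 3 or TR11B_KO replicate 3 (adjusted p up to 0.0823) and with library totals alone (adjusted p = 0.0502). In OGT_KO, 2 heat shock genes rose and 3 fell (3 and 6 adjusted over the list alone; adjusted p = 0.428). There too DNAJB1 and HSPA8 lay below all NC libraries and HSPE1 above them, while HSPH1 did not lie below.

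Lists tied to osteoprotegerin and inflammation were not called in TR11B_KO. In the osteoprotegerin axis, 2 of 8 tested genes fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.467), among them the TRAIL receptor gene TNFRSF10B (−0.86 ± 0.20, adjusted p = 0.00631). Of 23 NF-kB targets, 3 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.233), with rises of LTB and CSF2 (2.19) and a fall of IL6 (−1.40). Of 15 genes of MHC class I presentation, 8 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.059), with rises of HLA-F (1.10) and PSMB10 (1.01); reads of HLA genes are shared between close copies and alleles. Of 20 interferon response genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.325), with IRF7 (1.63) and IFI6 (1.55) higher. The p53 targets MDM2 (1.5), BBC3 (1.06) and PHLDA3 rose, though BBC3 did not pass with the GC offset or both offsets (0.38 and 0.39, adjusted p up to 0.101), in a list of 26 with 8 rising and 5 falling, also when adjusted over the list alone (adjusted p = 0.233). MDM2 and BBC3 lay above all NC libraries in OGT_KO as well, where PHLDA3 fell. PHGDH, which opens serine synthesis, rose by 2.16 ± 0.21, and the sterol reductase gene TM7SF2 rose by 1.66 ± 0.29. GFPT2 fell by 1.57 ± 0.35 (adjusted p = 0.00528), as in OGT_KO.

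The knockouts were then compared with each other, in the same fit of all 9 libraries. NC therefore entered the filter, the scaling and the shared spread, though not the contrast itself. SPATC1L and TMEM98 were low in OGT_KO alone, with 937, 1347 and 1067 and with 530, 565 and 404 counts in TR11B_KO. IGFBP4, a binding protein of insulin-like growth factors, was at 23 ± 1.47 CPM in OGT_KO, 117 ± 6.68 in NC and 563 ± 75.4 in TR11B_KO (SD, n = 3), and differed between the knockouts by −4.61 ± 0.19 (SE; adjusted p = 4.98e-09 in edgeR). SMO was lower in OGT_KO by 5.37 ± 0.29. Higher in OGT_KO than in TR11B_KO were VCAN (4.73 ± 0.38), TNC (4.68 ± 0.30), ANXA3 (4.13 ± 0.45), EPAS1 (3.95 ± 0.40) and the adhesion molecule gene L1CAM (3.49 ± 0.25).

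The direct test called 4174 of 12574 genes, 2104 higher and 2070 lower in OGT_KO, and 2355 of them differed at least 2-fold. Without NC replicate 1, 2 or 3 it called 3680, 3729 and 3840, and a fit of only the 2 knockouts called 3145. Groups did not overlap for 44.9% of the tested genes, where chance gives 10%. Of the lists, 7 were called by camera, and 0 with an estimated correlation, where 2 passed an unadjusted p under 0.05; fry passed 23. Relative to TR11B_KO, OGT_KO was higher in mitosis genes (17 of 36 higher and 1 lower, and 18 and 1 adjusted over the list alone; adjusted p = 0.000101, and adjusted p = 0.323 with an estimated correlation). It was higher in OGT partners (12 of 23 and 0 lower, also adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.323 with an estimated correlation). It was lower in ribosomal protein genes (21 of 46 and 0 higher, also adjusted over the list alone; adjusted p = 1.93e-06, and adjusted p = 0.323 with an estimated correlation) and in oxidative phosphorylation genes (15 of 38 and 2 higher, and 17 and 2 adjusted over the list alone; adjusted p = 0.0191, and adjusted p = 0.44 with an estimated correlation). With 1 library left out, the lower genes ranged from 15 to 36 for ribosomal proteins and from 5 to 24 for oxidative phosphorylation. The higher mitosis genes ranged from 11 to 21. The mesenchymal and matrix lists were higher in OGT_KO, with 7 of 13 genes higher and 3 lower and with 10 of 24 higher and 4 lower, and NF-kB targets were lower, with 8 of 23 lower and 2 higher, all the same counts as adjusted over the list alone. Each passed at 0.049 (adjusted p = 0.323, 0.44 and 0.323 with an estimated correlation). The direct fold changes had a rank correlation with length of 0.333 across genes, and of 0.352 among genes with an average log2 CPM of at least 2, with a median length of 5890.5 bases for higher and 2764 for lower calls. With the length offset the median went from −0.51 to −0.29 for ribosomal protein genes (13 lower and 0 higher; adjusted p = 0.0333, the highest of their alternatives), from 0.84 to 0.52 for OGT partners (adjusted p = 0.048, and up to 0.0776, with both offsets) and from −0.50 to −0.26 for oxidative phosphorylation genes, whose call was lost (adjusted p = 0.305). That call was also lost without TR11B_KO replicate 1 (adjusted p = 0.117), with both offsets (0.155) and with library totals alone (0.0504). The matrix call was lost without any of the NC replicates 1, 2 and 3, OGT_KO replicate 2 or TR11B_KO replicate 1 (adjusted p up to 0.206), and with the length offset (0.297), both offsets (0.253), RLE size factors (0.0778), the replicate block (0.0767) and the filter of CPM at least 1 in 3 libraries (0.0682). The mesenchymal call was lost without NC replicate 1 or 2, OGT_KO replicate 1 or 2, or TR11B_KO replicate 1 or 3 (adjusted p up to 0.193), with library totals alone (0.071) and with no low-count filter (0.152), where 16 genes were tested and the median turned from 1.11 to −0.02. The NF-kB call was lost without NC replicate 1, 2 or 3, OGT_KO replicate 2, or TR11B_KO replicate 1 or 3 (adjusted p up to 0.0868), and with both offsets (0.155), the length offset (0.098), the GC offset (0.0873), the replicate block (0.0626), the filter of CPM at least 1 in 3 libraries (0.0622), library totals alone (0.0609) and RLE size factors (0.0541), and its median of −0.06 was 0.22 with library totals alone and 0.04 with the GC offset. Without OGT_KO replicate 2 the test called 2401 genes, and scaling by library totals alone gave a median of 0.314 in place of 0.056 and 3084 higher and 1268 lower genes. RLE size factors moved the median the other way, to −0.014, with 4201 calls.

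A set of genes changed alike in both knockouts. NNMT fell by 4.09 in OGT_KO and 2.31 in TR11B_KO, PINX1, an inhibitor of telomerase, by 2.42 and 2.31, the actin-binding protein gene TAGLN by 2.20 and 1.89, ARHGAP23 by 1.90 and 1.79, the monoacylglycerol lipase gene MGLL by 1.67 and 1.73, and TRIM68 by 1.63 and 2.01. Creatine kinase B (CKB) rose by 1.66 and 1.84, VASH1 by 2.39 and 1.52, RTN4RL2 by 1.62 and 2.79, and the transporter gene SLC16A13 by 1.99 and 1.49. In all, 300 genes rose in both and 471 fell in both, 771 together. Independent lists of the same sizes would share 137.7 and 181.2, and groups simulated without effects against the same NC libraries shared 0, so neither number alone is the one to set against 771. A further 214 genes changed in opposite directions, where independent lists would give 316.5. All 214 were called in the direct test, which opposite changes in the same fit make nearly certain, so this is no added support.

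Part of the excess may come from the shared NC libraries, which are too few to be split. The fold changes of the 2 comparisons had a correlation of 0.226 across genes, where simulated unchanged groups had 0.494, and a covariance of 0.172, where the simulation gave 0.067 and the difference was 0.104. The 771 became 284 and 294 without NC replicate 1 or 2, 368, 443 and 370 without OGT_KO replicate 1, 2 or 3, and 1205 and 1512 without TR11B_KO replicate 1 or 2. The 214 became 77, 66 and 91 without NC replicate 1, 2 or 3, 117, 112 and 127 without OGT_KO replicate 1, 2 or 3, and 364 and 537 without TR11B_KO replicate 1 or 2.

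**Figure D4:**
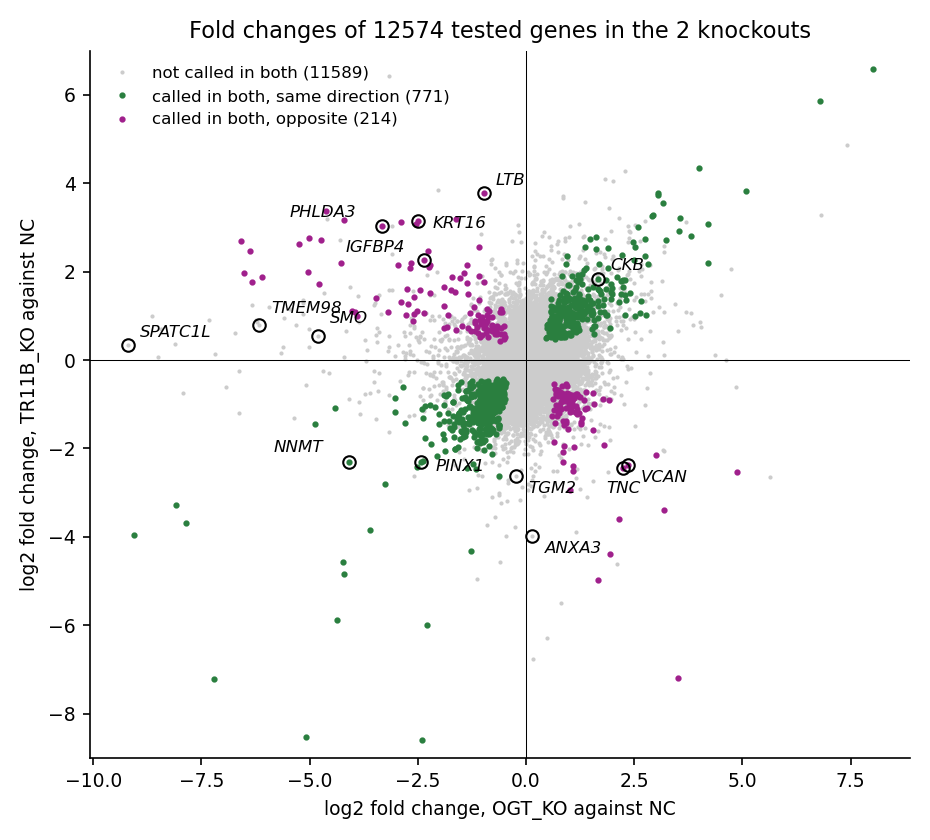
Log2 fold changes of 12574 tested genes in OGT_KO (horizontal axis) and TR11B_KO (vertical axis) against NC, with genes called in both in the same direction (771) in green, in opposite directions (214) in purple, and others in grey. Circled genes are named in the text; IGFBP4, PHLDA3 and KRT16 lie at lower values in OGT_KO and higher ones in TR11B_KO, and VCAN and TNC the other way.

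Fold changes also differed between chromosome arms, and 5 arms were taken up after their medians had been seen. Relative to all other genes, the median of 118 tested genes of 21q, the arm of SPATC1L, was shifted by −0.55 in OGT_KO (95% bootstrap interval over genes −0.67 to −0.35), with 35 genes falling and 2 rising. The shift was 0.39 (0.28 to 0.51) for 131 genes of 18q and 0.29 (0.21 to 0.40) for 109 genes of 20p, with 24 and 15 genes rising and 5 and 1 falling. In TR11B_KO the shift was −0.67 (−0.79 to −0.54) for 200 genes of 13q, with 66 falling and 4 rising, and −0.54 (−0.69 to −0.30) for 99 genes of 5p, with 32 falling and 7 rising. In camera over 41 arms the adjusted p was 5.22e-08 for 21q, 0.000728 for 18q, 0.00531 for 20p, 1.33e-06 for 13q and 0.000272 for 5p. With an estimated correlation the adjusted p was 0.285, 0.754, 0.219, 0.937 and 0.937. Every library of the group lay on the same side: the medians against NC were −0.55, −0.51 and −0.57 for 21q, and −0.36, −0.76 and −0.69 for 13q. On these 5 arms, libraries of the other knockout ran from −0.356 to 0.256. The lowest was TR11B_KO replicate 2 on 20p, where replicates 1 and 3 were at 0.057 and −0.052. An arm median can therefore move by more than the 20p shift in 1 library alone. Camera also called 2p, 7q, 19q, 20q and 22q in OGT_KO, and 19p and 19q in TR11B_KO, none of which passed with an estimated correlation (adjusted p = 0.754, 0.219, 0.995, 0.285, 0.754, 0.937 and 0.937).

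**Figure D5:**
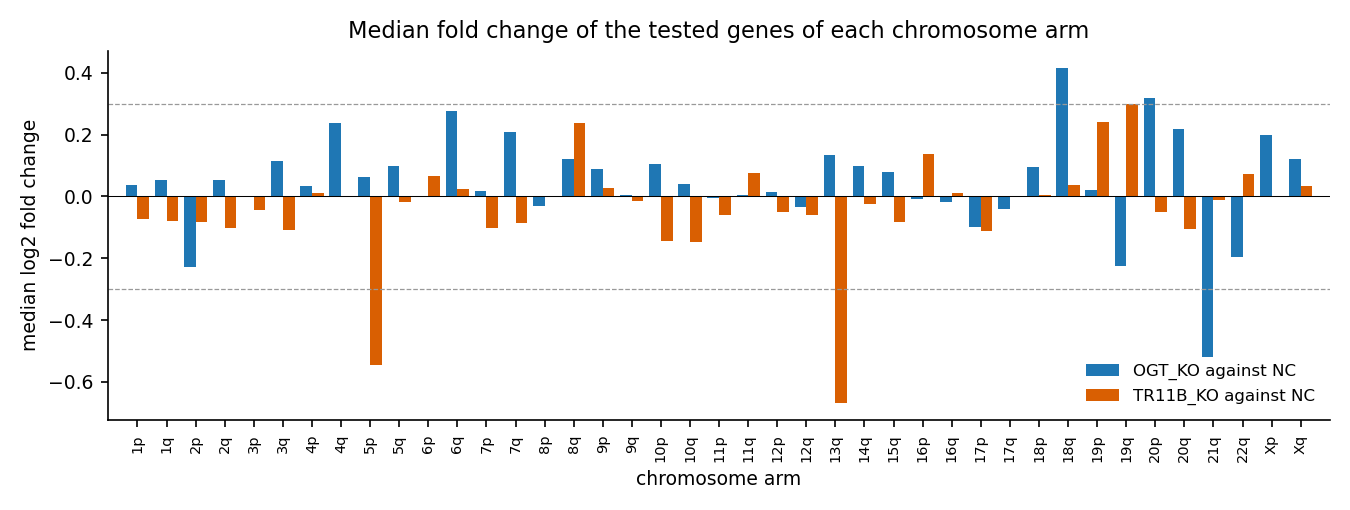
Median log2 fold change of the tested genes of each chromosome arm in OGT_KO and TR11B_KO against NC, with dashed lines at 0.3 and −0.3. In OGT_KO 21q lies below and 18q and 20p above these lines, and in TR11B_KO 5p and 13q lie below them.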

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

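The offset settings were chosen only after the result was seen; each value is from the direct edgeR test of the difference between the knockouts. The following 5 genes stood out because they passed the test against NC in both knockouts, in opposite directions, and had the largest such changes by the rule fixed beforehand. Because they were chosen by those changes in the same fit, their direct p-values are no independent support. PHLDA3, a p53 target that restrains AKT, was lower in OGT_KO than in TR11B_KO by −6.38 on the log2 scale (adjusted p = 5.89e-07), with 0.537 ± 0.409 CPM (SD, n = 3) in OGT_KO, 5.41 ± 0.374 in NC and 44.6 ± 17.6 in TR11B_KO. KRT16, a keratin of stressed and wounded epithelium, differed by −5.63 (adjusted p = 2.32e-07), at 0.283 ± 0.0592, 1.61 ± 0.25 and 14.2 ± 5.27 CPM in the same order. IGFBP4 differed by −4.61 (adjusted p = 4.98e-09). In the other direction, VCAN differed by 4.73 (adjusted p = 1.57e-06), at 133 ± 23.6, 26.1 ± 4.77 and 5.05 ± 2.85 CPM, and TNC by 4.68 (adjusted p = 2.66e-07), at 19.6 ± 1.55, 4.14 ± 1.2 and 0.76 ± 0.23 CPM. All 5 passed in the same direction in each comparison under all 22 alternatives, which include each library left out and the length, GC and combined offsets. Other technical explanations were not tested for these genes singly.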

How the results depend on the processing

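The settings with length or GC offsets, and all alternatives for lists in the direct comparison, were chosen after seeing the data; all others were fixed beforehand. With 1 library left out, calls ranged from 1072 to 4536 in OGT_KO, 1813 to 4463 in TR11B_KO and 2401 to 5307 in the direct comparison, genes changed alike from 284 to 1512, and lists from 5 to 8 and 7 to 11. Fits of only the 2 groups gave 5095 calls in OGT_KO and 2251 in TR11B_KO, which reverses their order in the shared fit. The shared fit pooled the spread of groups that differed in it. Across genes, the SD of a library's log2 deviation from its replicates was 0.556 to 0.851 in TR11B_KO. It was 0.437 to 0.462 in OGT_KO and 0.456 to 0.517 in NC. A pooled spread works in this direction, but its part was not tested separately. By construction, a 2-fold threshold left 1230, 1745, 2355 and 267 (the last changed alike), and an adjusted p under 0.01 left 947, 1631, 2264 and 259. The GC offset gave 1278 genes changed alike and 365 in opposite directions (350 with both offsets), and the cause was not tested. Of the latter genes, 86 passed the 2-fold threshold and 60 an adjusted p under 0.01. Camera with an estimated correlation called 0 and 0 lists, though 18 and 25 passed fry, which does not compare lists with other genes. DESeq2 called 2780, 3908 and 4638 genes, giving no adjusted p for 4503, 4157 and 3811. On FPKM + 1 in limma, the calls were 1005 higher and 806 lower in OGT_KO, 1095 and 1865 in TR11B_KO, and 1935 and 1000 directly; there, as with library totals, the shares of higher genes moved by over 10 percentage points, but in limma the test and the genes changed too. Of up to 155 gene results with a value in a setting, 144 to 155 kept their side of the threshold and direction. Most of these genes were chosen for their changes in the main fit, so this says little about the calls at large. With 1 library left out, 45.9% to 100% of all OGT_KO calls were called again. For TR11B_KO this was 51.8% to 92%, and for the direct comparison 56.6% to 92.9%. The value of OGA in TR11B_KO, which did not pass, turned positive without TR11B_KO replicate 2 (0.05, 0.048 unrounded) and with the length offset (0.001) or both offsets (0.118), in a range from −0.575 to 0.048 with 1 library left out; the cause was not tested. The replicate numbers did not pair the libraries: residual correlations of same-numbered libraries ran from −0.2 to 0.07, 0 pairs were over 0.1, and 0 libraries correlated best with their own number. With the number as a replicate block the calls were 1609, 2612 and 3403, with 469 changed alike and 116 in opposite directions. Depth limited low genes such as TNFRSF11B, and the simulations recovered few 1.5-fold changes.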

Other observations

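The tests on OGT mRNA, on sequencing depth of TR11B_KO replicate 2, and on 18q, 20p and 21q singly were chosen only after the result was seen, as were the 5 chromosome arms, the offsets and the other reference groups. Lists of markers of other cells were too small to be tested as lists. Of 20 immune markers 9 were in the count table and 1 passed the filter, of 15 fibroblast markers 8 and 2, of 10 endothelial markers 6 and 1, and of 15 neural or embryonic kidney markers 2 and 2; a marker missing from the table says nothing about its level. Those last 2, SYP and PAX2, named after their values were seen, averaged 62.7 and 65.2 CPM in NC, and rose in OGT_KO to 134.7 and 122.9 CPM (log2 fold changes 1.10 and 0.91). SYP rose in TR11B_KO by 0.66 (adjusted p = 0.0235), but not past the threshold in 5 of 22 alternatives: without NC replicate 1 or 2 (0.63 and 0.62, adjusted p = 0.0913 and 0.0952, the highest of its alternatives), and with the replicate block, the length offset or only the 2 groups compared. The immediate early genes, which were not called as a list in OGT_KO (adjusted p = 0.165), included 7 of 17 that rose and 2 that fell, also when adjusted over the list alone. The apoptosis regulators included 5 of 24 that rose and 3 that fell in TR11B_KO (6 and 4 adjusted over the list alone; adjusted p = 0.115).

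Gene calls were weighed against trends of fold change with length and GC content, because TR11B_KO showed such a trend with length. With the length offset, 2282 genes were called in OGT_KO and 2785 in TR11B_KO, and with the GC offset 3277 and 4346, against 2303 and 3469 without, which argues against either trend as the whole source of the calls. Single lists were another matter: with the length offset the median of the ribosomal protein genes went from 0.56 to 0.19. Most of that rise may thus belong to a length trend of technical or biological origin, which cannot be separated here. How much does depends on the setting. In the direct comparison their median was −0.51, against −0.29 with the length offset and −0.41 with both offsets (22 lower and 1 higher). The 10 splits of 6 libraries are too few for a share under 0.05. In fits of the 2 groups the real split called 5095, 2251 and 3145 genes in OGT_KO, TR11B_KO and the direct comparison, and the highest other split 0 in each; as many genes came from 1, 1 and 1 of 10 splits. For lists, the real splits called 5 and 8 and the highest others 5 and 5, with as many from 3 and 1 of 10. Of 100 assignments of the 9 libraries to groups, 1, the real one, gave as many as 771 genes changed alike, and the highest other gave 537. This argues against chance assignment of libraries to groups. The other assignments mixed libraries of differing groups, so the ranking cannot separate the overlap from the effect of the shared NC libraries. It also says nothing specific to NC as the reference, since the same groups gave 1174 genes with OGT_KO and 1883 with TR11B_KO as the reference.

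Whole-arm copy number differences between the cell populations are a candidate explanation for the shifted arms. In both parts of each arm, divided at its middle gene, at least 72.7% of genes lay on the shifted side for 21q, 18q and 20p in OGT_KO and at least 68% for 5p and 13q in TR11B_KO. A gain or loss of the arm would give this. However, the arms were chosen by their medians, so a majority on that side follows from the choice. Only its presence in both parts bears on the question, and no other arm was measured this way. Length and GC trends are argued against for 20p and 21q, whose shifts with both offsets were 1.305 and 0.93 times those without, and for 5p and 13q, where the smaller ratio was 0.74; for 18q, and so for the 3 arms of OGT_KO as a set, the ratio of 0.659 fell between the bounds set and leaves this open. Arms with a median beyond 0.3 held 3.2% and 2.8% of the called genes in the direction of the call. Arms shifted that far thus held too few to account for the calls as a whole. The shares leave out the other arms called by camera. In OGT_KO, for example, 107 genes of 19q fell and 27 rose, and on 2p 65 fell and 17 rose. In TR11B_KO, 127 genes of 19q rose and 32 fell, with a median of 0.3. Shares with these arms included were not computed, so smaller arm shifts stay open. A loss of the segment beyond the targeted site is argued against too, since genes from the target to the chromosome end had medians above those of other genes. The differences were 0.128 (95% bootstrap interval over genes 0.042 to 0.195) for OGT and 0.309 (0.211 to 0.449) for TNFRSF11B. Of the 134 genes beyond TNFRSF11B, 33 rose and 13 fell in TR11B_KO, while in OGT_KO their difference was 0.002 (−0.087 to 0.085). Whether that segment was gained in TR11B_KO was not tested. No DNA data were used here, and a regulatory effect of either knockout on the shifted arms stays open, as untested.

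OGT mRNA was lower in TR11B_KO, and without offsets its log2 fold change of −0.17 in OGT_KO did not pass (adjusted p = 0.607 in edgeR). With both offsets it passed in OGT_KO too (−0.448, adjusted p = 0.0258) and the direct difference did not pass (0.188, adjusted p = 0.305), so that part rests on the setting. An exchange of the 2 labels could give this, but cannot be told apart from correct labels, since TNFRSF11B had 1 count in OGT_KO and 4 in TR11B_KO (exact two-sided binomial p = 0.375), and edits can leave mRNA levels as they were. Length and GC trends are argued against for the fall in TR11B_KO, which was −0.99 without offsets and −0.636 with both (adjusted p = 0.00363, and at most 0.027 over all alternatives). An effect of the TR11B knockout on OGT stays open and was not tested apart from the labels.

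TR11B_KO replicate 2 stood apart from replicates 1 and 3. On genes that separated those 2 from OGT_KO its median position was 0.857 (0.812 to 0.901), where 0 is OGT_KO and 1 is the mean of replicates 1 and 3, and on genes that separated them from NC it was 1.044 (0.991 to 1.126). The rank correlation of its deviation with GC content was 0.309, while TR11B_KO replicate 1 and OGT_KO replicate 2 had −0.474 and −0.444. Thinned to the lowest library total it had 13799 genes with a count, fewer than the 14208 to 14532 of the other libraries.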
